A study of Homo sapiens with 26 samples.

How the data were processed

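Total RNA from normal human bronchial epithelial (NHBE) cells, primary cells of the airway lining grown in culture, was measured on 26 one-colour arrays. The arrays fall into 13 groups of 2. Cells received cigarette smoke condensate (CSC) A or B together with S9 and were taken at 2, 4, 8 or 12 h, or received S9 alone and were taken at the same times, or were untreated at 0 h. S9 is the supernatant of a liver homogenate that carries drug-metabolizing enzymes and is added to activate compounds that need metabolism. The labels give no dose of either condensate, and do not say what distinguishes A from B. They do not say whether replicates came from separate cultures or donors, so the spread between replicates may be technical, and the p-values measure only that spread.

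The deposited values are spot intensity on a linear scale, in 22175 rows, with a background already taken off. This was read from the values themselves, which run from below 0 to just under the top of a 16-bit scanner. The scanner, the background method and any scaling or centring by the authors are not given in the sources used here. The table was used as the only record of these arrays. Array medians ran from 71.3 to 358, so the deposited intensity is not normalized between arrays. All 26 columns were matched to samples through the table's own sample names, and 0 columns were left unmapped.

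The design fixed before the data were examined kept the values as deposited unless the array medians showed a table that was not normalized. They did, so quantile normalization between the 26 arrays was used for the reported values, and the unnormalized values became an alternative. Values below 0 were set to the floor of 0, and log2(intensity + 16) was taken. A fold change is therefore on the log2(intensity + 16) scale, which understates the change of dim probes. Rows in the lowest 40% by mean over all arrays were left out, which kept 13305 rows. Of these, 1 row per gene symbol was tested, the brightest, and only rows with a single symbol, which left 9708 probes. Their number of arrays limits the precision: the model had 13 residual degrees of freedom.

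Symbols came from the platform's annotation table. It gives 1 symbol for 17033 rows and several for 160, and 4982 rows are unnamed here. Its entrez identifiers were found in the gene table at hand for 16946 rows. Whether the annotation belongs to the rows was tested on the brightness of gene families whose expression is known to be wide or tissue-restricted, on different rows with the same symbol, and on rows that share an accession. The result, given at the start of the report, did not bear the annotation out. For that reason a symbol below only says how the annotation names a row, and no statement about a gene or a pathway is drawn from it.

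Differences were tested with limma's lmFit and eBayes in R 4.3.3 (limma 3.58.1, statmod 1.5.0), in 1 model with a mean for each of the 13 groups. Every limma p was adjusted by the Benjamini-Hochberg method over the 9708 probes, and a probe is called at an adjusted p under 0.05. For each condensate the contrast was condensate with S9 minus S9 only at the same time, at each time and averaged over the 4 times. Condensate A was set against B in the same way, and S9 only against untreated cells at 0 h. Limma's F test asked whether a contrast changed between the 4 times. Errors of log2 differences are standard errors (SE) from the model. Means of log2 intensity are given with the SD over arrays. Over the 4 times this SD includes change with time.

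The rule for naming probes took the 10 largest rises and falls of each averaged contrast among called probes with the same sign at all 4 times, those of single times and of 25 gene lists, and the probes of CYP1A1, CYP1B1, HMOX1 and NQO1 for the condensates. Because the annotation was not borne out, the report prints only the first 2 rises and falls of each averaged contrast, the 4 fixed genes, and 1 probe from an F test named after its values were seen. The closing section also names the 3 largest rises of a comparison chosen later. The 25 lists covered stress, xenobiotic, cell cycle and cell type genes. They were tested on the 4 averaged contrasts with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry. No probe is named for its place in a list.

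Probes were also searched for a gap between arrays: a probe counted when its sorted log2 values had a gap of over 0.9 that parted the arrays. The pattern of arrays on each side of the gap was then tallied. This search, and everything that rests on it, was chosen after the data were seen. Other alternatives were no filter, a filter at the 60th percentile, pseudocounts of 1 and 64, all rows in place of 1 per symbol, an intensity trend in eBayes, the replicate number as a block, a fit on only the arrays of a comparison, scaling to the 75th percentile, centring of the 48 subgrids of the array, a term for the array sets, leaving out the 3 arrays with the most spots below 0, and leaving out each array in turn.

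The fit was tested on simulated data with 200 changed probes among 9708. For condensate A against S9 only over the 4 times it recovered 66.2% of changes of 0.5 log2, 97.5% of changes of 1 log2 and 100% of changes of 2 log2. It made 13 false calls there. At 2 h alone, with 2 arrays against 2, it recovered 8.8% of changes of 0.5 log2, 56.2% of changes of 1 log2 and 97.5% of changes of 2 log2, with 3 false calls. Genes on the sex chromosomes that would show a donor's sex were left out of every table.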

Results

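Expression in NHBE cells was measured on 26 arrays: CSC A with S9, CSC B with S9 and S9 only at 2, 4, 8 and 12 h, and untreated cells at 0 h, with 2 arrays in each of the 13 groups. Replicate arrays correlated across rows with Spearman coefficients of 0.96 to 0.987, where rows are not independent replicates. The share of spots below 0 was 0.19% to 0.92% on the 8 S9 only arrays and untreated replicate 2. On the other 17 arrays it ran from 1.66%, on CSC B at 12 h replicate 2, to 15.89%, on CSC B at 8 h replicate 1.

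The gene names attached to the rows ordered their brightness weakly at most. Ribosomal protein probes, for transcripts among the most abundant in any cell, had a median intensity percentile of 65.7, and probes for olfactory receptors, which airway epithelial cells hardly use, a median of 48.1. Translation factor probes had a median of 49.2. Over 10 families, the chance that a probe of a widely expressed family (194 rows) was brighter than one of a tissue-restricted family (202 rows) was 0.543, with a 95% interval of 0.487 to 0.6 and a two-sided permutation p of 0.132 over 10000 permutations. The probe annotated to EEF1A1, a translation factor of all cells, stood at percentile 8.5 and the one annotated to ALB, the liver's serum albumin, at 76.8. Among other widely expressed genes, the probes annotated to GAPDH and RPS9 were brighter, at 83.3 and 61.3. Those annotated to LDHA and RPL5 were dim, at 18.8 and 29.9. The probes annotated to KRT5 and KRT14, keratins of basal epithelial cells, stood at 68.5 and 94.2. Different rows with the same symbol correlated in mean log2 intensity at r = 0.083 over 1550 pairs (rho = 0.079, permutation p = 0.0009), and different rows with the same accession at r = 0.319 over 61 pairs (rho = 0.337, permutation p = 0.0128). In the 22 sets of rows with identical values that had an accession, all rows of a set shared it. All results below are therefore results on probes, and a symbol says only how the annotation names one.

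**Figure D1:**
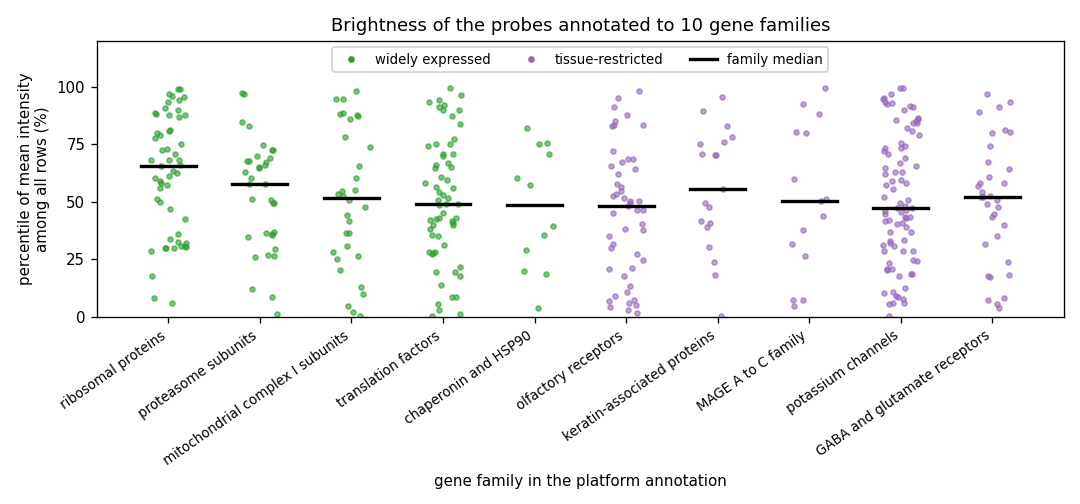
The vertical axis is the percentile of a row's mean intensity among all rows (%), each point is 1 row, and the horizontal axis gives its family in the annotation. Black lines are family medians, from 47.3 for potassium channels to 65.7 for ribosomal proteins, and the 5 widely expressed families overlap the 5 tissue-restricted ones.

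The arrays fell into 3 sets on probes that were bright on some arrays and dim on others. In all, 102 probes had a gap of at least 0.9 log2 between arrays. The most frequent pattern, with 38 probes, parted the 8 S9 only arrays and untreated replicate 2 from the other 17 arrays: 34 of them were brighter on the 17 arrays, and the median difference was 2.1 log2. The next, with 17 probes, parted the 6 arrays of CSC A at 2, 4 and 8 h, on which all 17 were dimmer, by a median of 2.6 log2. The pattern after these held 8 probes. Both untreated arrays carry the same label and lie in different sets, so the first pattern follows the array and not the treatment alone. S9 only and the condensates share no set. The untreated pair is the sole link between the set of S9 only and that of CSC B and of CSC A at 12 h, and no untreated array lies in the set of CSC A at 2, 4 and 8 h. The array sets were defined from the data, and the labels name no batch.

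**Figure D2:**
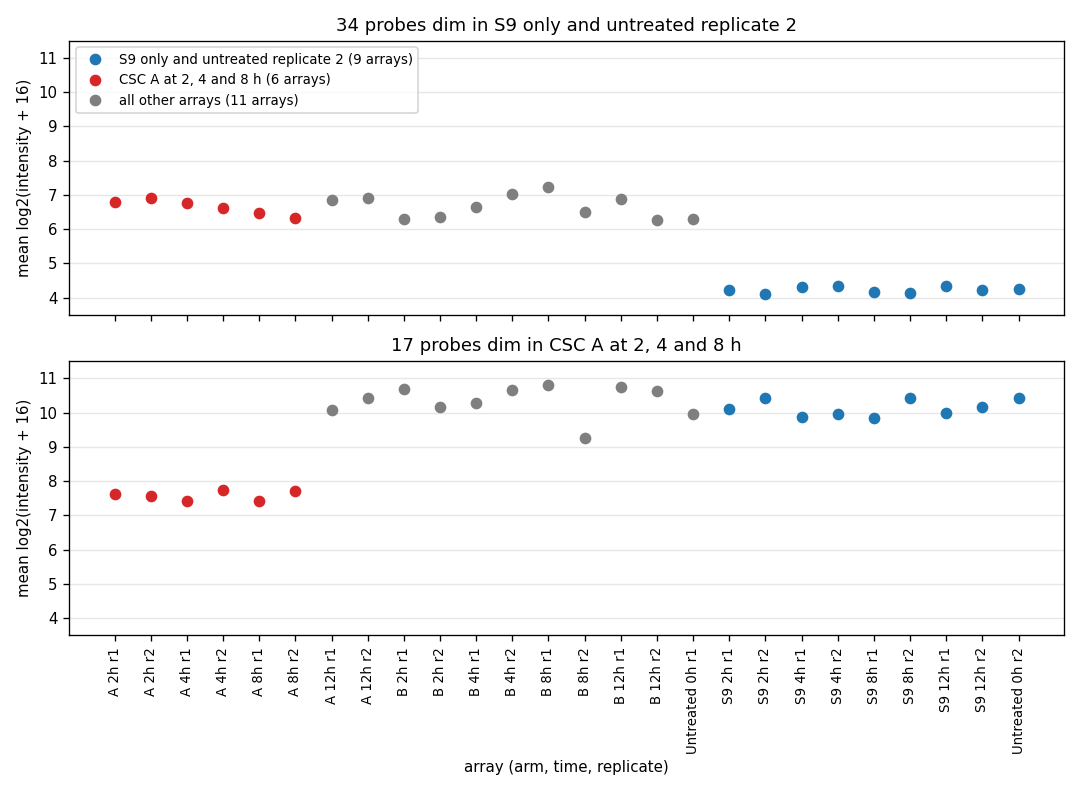
The vertical axes give the mean log2(intensity + 16) of 34 probes (upper) and 17 probes (lower) on each of the 26 arrays along the horizontal axis, each point being 1 array (A and B are CSC A and CSC B with S9, S9 is S9 only, r is the replicate). On the 34 probes the 9 arrays with S9 only or untreated replicate 2 lie between 4.1 and 4.35 and all others between 6.26 and 7.23, and on the 17 probes CSC A at 2, 4 and 8 h lies between 7.42 and 7.74 and all others at 9.25 or above.

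CSC A with S9 was set against S9 only to ask how the condensate changed expression. Over the 4 times 1565 probes were higher and 1912 lower with CSC A, of 9708 tested (8 arrays against 8, limma adjusted p under 0.05). Among these 122 rose and 97 fell by at least 2-fold, the median size of a called difference was 0.457 log2, and the median SE over tested probes 0.114. The 2 rises that ranked first were on the probe annotated to ADAM15 (a membrane metalloprotease), from 4.18 ± 0.51 to 12.79 ± 0.23 (SD, n = 8), a difference of 8.61 with an SE of 0.76 and a limma adjusted p of 1.72e-06, and on that annotated to TUBB6 (a beta tubulin), from 4 to 8.91, a difference of 4.91 with an SE of 0.44. With S9 only the TUBB6 probe lay at the floor of the scale on all arrays and the ADAM15 probe at or near it, so neither was above background there. Their sizes and ranks are set by the pseudocount and are no measured fold changes: with a pseudocount of 64 the ADAM15 and TUBB6 differences were 6.74 and 3.04, and with 1 that of ADAM15 was 12.18. Both are among the 38 probes that part the S9 only arrays and untreated replicate 2 from the rest. Among called probes with the same sign at all 4 times, the 2 largest falls were on the probe annotated to PSD3, by -2.6 (SE 0.29, limma adjusted p = 9.92e-06), and on that annotated to CDCA5, a cohesion factor of mitosis, by -1.93 (SE 0.14, limma adjusted p = 3.49e-07). The PSD3 probe came near the floor with CSC A, at 4.52 at 2 h and 5.14 at 4 h, so its size depends on the pseudocount, with -3.42 at 1 and -1.86 at 64. The CDCA5 probe is among the 17 that part CSC A at 2, 4 and 8 h. Other probes fell by more than CDCA5 on average without meeting that condition, such as another of the 17, annotated to ERICH6B, which fell by -4.16, -3.91 and -3.73 at 2, 4 and 8 h and not at 12 h.

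The probes annotated to the 4 fixed genes, chosen because smoke is known to raise those genes, were not called higher. The probe annotated to HMOX1, heme oxygenase of the oxidative stress response, was lower with CSC A, at 8.78 ± 0.22 against 9.17 ± 0.18 (SD, n = 8), a difference of -0.4 with an SE of 0.11 and a limma adjusted p of 0.0115. That annotated to CYP1B1, a target of the aryl hydrocarbon receptor, differed by 0.17 (SE 0.11, limma adjusted p = 0.212). The probes annotated to CYP1A1, another such target, and to NQO1, an antioxidant enzyme, stood at intensity percentiles 8.1 and 0.4 and were not tested. With a term that sets the S9 only arrays and untreated replicate 2 apart, 3 probes passed for CSC A over the 4 times, and the differences of the ADAM15, TUBB6 and CYP1B1 probes turned to -0.38, -0.27 and -0.11. The PSD3 and CDCA5 differences were then -0.87 and -1.62 and no longer passed. The HMOX1 difference was then -0.55 and no longer passed, and without normalization it was -0.43 and did not pass either. Without normalization 414 probes were higher and 1027 lower.

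At single times, with 2 arrays against 2, the numbers of probes higher and lower with CSC A were 783 and 782 at 2 h, 97 and 182 at 4 h, 52 and 110 at 8 h and 205 and 364 at 12 h. Limma's F test found 39 probes whose difference from S9 only changed between times, and 1 within 2, 4 and 8 h, which lie in 1 array set for CSC A. Single arrays moved these counts. At 2 h the total of 1565 became 163 without S9 only replicate 2, 900 without S9 only replicate 1 and 307 without CSC A replicate 1. At 4 h the total of 279 became 36 without CSC A replicate 1, and 118 and 57 without S9 only replicates 1 and 2. The total of 162 at 8 h became 39 and 69 without CSC A replicates 1 and 2, and 75 and 27 without S9 only replicates 1 and 2. At 12 h the total of 569 became 199 and 315 without CSC A replicates 1 and 2, and 88 and 11 without S9 only replicates 1 and 2. The 39 probes that changed between times became 79 without CSC A at 2 h replicate 2 and 9 without CSC A at 12 h replicate 1. They became 23 without S9 only at 2 h replicate 2, 66 without S9 only at 4 h replicate 1, and 3 and 1 without S9 only at 12 h replicates 1 and 2. Without normalization the numbers higher and lower were 4 and 47 at 4 h, 3 and 46 at 8 h and 4 and 56 at 12 h.

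**Figure D3:**
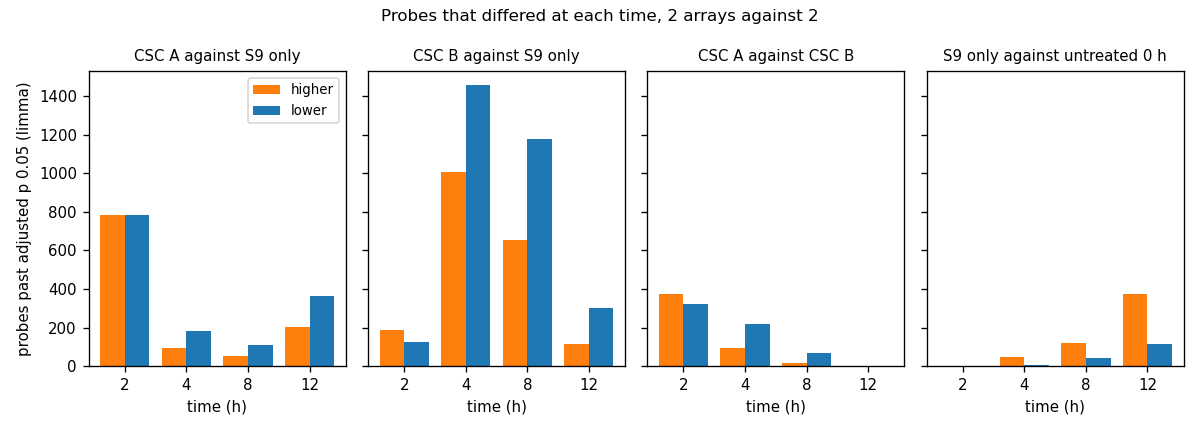
Bars count probes past a limma adjusted p of 0.05 (vertical axis), higher in orange and lower in blue, at 2, 4, 8 and 12 h (horizontal axis), with 2 arrays against 2 in each of 4 comparisons. CSC A against S9 only peaks at 2 h (783 higher, 782 lower), CSC B against S9 only at 4 h (1005 higher, 1455 lower), CSC A against CSC B falls to 0 at 12 h, and S9 only against untreated reaches 372 higher and 116 lower at 12 h.

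CSC B with S9 against S9 only gave 2265 probes higher and 2975 lower over the 4 times (8 arrays against 8, limma adjusted p under 0.05). At least 2-fold differences were 237 rises and 155 falls, and the median size of a called difference was 0.503 log2. The largest rises were on the same pair of probes as for CSC A, 8.41 (SE 0.76, limma adjusted p = 1.55e-06) on the one annotated to ADAM15 and 4.84 (SE 0.44) on the one annotated to TUBB6. Both are again differences from the floor, at 6.54 and 2.98 with a pseudocount of 64, and 11.99 for ADAM15 with 1. The largest falls were on the probe annotated to CDH7, a cadherin, by -1.74 (SE 0.15, limma adjusted p = 1.32e-06), from 8.08 ± 0.25 to 6.35 ± 0.32 (SD, n = 8), and on that annotated to UROS, an enzyme of heme synthesis, by -1.69 (SE 0.12, limma adjusted p = 1.14e-07). The probe annotated to HMOX1 was lower by -0.74 (SE 0.11, limma adjusted p = 6.28e-05), and that annotated to CYP1B1 differed by -0.01 (SE 0.11, limma adjusted p = 0.949). With a term for the array sets 4 probes passed, the ADAM15 and TUBB6 differences turned to -0.58 and -0.34, and the CDH7, UROS and HMOX1 differences, at -0.56, -1.25 and -0.89, no longer passed. Without normalization 1004 probes were higher and 2456 lower.

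At single times CSC B gave 188 probes higher and 128 lower at 2 h, 1005 and 1455 at 4 h, 652 and 1179 at 8 h and 117 and 301 at 12 h. Scaling to the 75th percentile gave 355 and 114 at 2 h and 231 and 262 at 12 h. Centring of the subgrids gave 311 and 129 at 2 h and 278 and 417 at 12 h. Without normalization the splits were 3 and 11 at 2 h, 397 and 84 at 4 h, 29 and 437 at 8 h and 7 and 932 at 12 h. Limma's F test found 1 probe whose difference changed between times, the row annotated to ODAD1 (a dynein docking factor of cilia), with -0.71, 0.5, 1.78 and 1.5 at 2, 4, 8 and 12 h and a limma adjusted p of 0.00739. It was named after its values were seen. The F test passed 593 probes at an unadjusted p under 0.05, and its count of 1 became 0 without CSC B at 2 h replicate 2 or S9 only at 2 h replicate 2. The count became 3 without CSC B at 4 h replicate 1 and 4 without CSC B at 8 h replicate 2 or 12 h replicate 1. It became 17 without S9 only at 4 h replicate 1, and 2 without CSC B at 2 h replicate 1, 8 h replicate 1 or 12 h replicate 2, or without S9 only at 8 h replicate 2. The total of 316 at 2 h became 4 without CSC B replicate 2 and 7 without S9 only replicate 2. At 4 h 2460 became 8 without CSC B replicate 2, and 292 and 1214 without S9 only replicates 1 and 2. At 8 h 1831 became 68 without CSC B replicate 1, and 310 and 342 without S9 only replicates 1 and 2. At 12 h 418 became 13 without CSC B replicate 1, and 18 and 8 without S9 only replicates 1 and 2.

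Probes called for both condensates against S9 only mostly differed in the same direction. Of the 3477 and 5240 probes called, 1132 were higher in both and 1408 lower in both, where independent lists of these sizes would share 365.1 and 585.9, and 59 went opposite ways. Across the 9708 probes, which are not independent replicates, the log2 differences correlated at r = 0.744 (rho = 0.725). Both use the same S9 only arrays, and unchanged groups simulated against them gave r = 0.498 on average and at most 0.526 in 100 simulations. With the S9 only arrays split by replicate number, r was 0.761 and 0.624. The covariance was 0.1443, against 0.0086 in the simulations and 0.1464 and 0.1297 with the split arrays. A shift between array sets would enter both differences alike and is not removed by the split.

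CSC A was set against CSC B directly to ask whether the preparations differ. Over the 4 times 1331 probes were higher and 958 lower with CSC A (8 arrays against 8, limma adjusted p under 0.05), of which 1 rose and 101 fell by at least 2-fold. The falls that ranked first were on the probe annotated to PSD3, by -3.78 (SE 0.29, limma adjusted p = 3.52e-07), from 10.29 ± 0.71 with CSC B to 6.51 ± 2.08 with CSC A (SD, n = 8), and on that annotated to ERICH6B, by -3.14 (SE 0.22, limma adjusted p = 1.8e-07), which is among the 17 probes dim on the arrays of CSC A at 2, 4 and 8 h. Both sizes depend on the pseudocount, with -4.63 and -3.49 at 1 and -2.97 and -2.49 at 64. Of the 10 largest falls with the same sign at all 4 times, 8 were on probes among these 17. None of the 10 largest rises was on a probe that parts the array sets. The largest rises were 1.02 (SE 0.21, limma adjusted p = 0.00305) on the probe annotated to VPS13A and 1 (SE 0.26, limma adjusted p = 0.0114) on that annotated to TSPAN8, a tetraspanin of secretory cells. The TSPAN8 rise was 0.78 and no longer passed without the 3 arrays with the most spots below 0. The HMOX1 probe was higher by 0.34 with CSC A (SE 0.11, limma adjusted p = 0.0351), and this call was lost with no filter, without normalization (0.41), with subgrid centring (0.22), without the 3 arrays with the most spots below 0 (0.17), in a fit on only the arrays of the comparison, and when any 1 of 10 arrays was left out, with values from 0.24 to 0.35. These were CSC A at 2 and 4 h (both replicates), 8 h replicate 2 and 12 h replicate 1, and CSC B at 2 h replicate 2, 4 h replicate 2, 8 h replicate 1 and 12 h replicate 1. The CYP1B1 probe differed by 0.18 (SE 0.11, limma adjusted p = 0.215). Scaling to the 75th percentile gave 990 probes higher and 1229 lower. The total of 2289 became 1258 without CSC B at 4 h replicate 2, 1364 without CSC B at 8 h replicate 1 and 1502 without CSC B at 12 h replicate 1. It became 1524 without CSC A at 8 h replicate 2 and 1522 without CSC A at 12 h replicate 1.

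In the reported setting, fewer probes passed the adjusted threshold between the condensates at each later time. By limma 374 were higher and 320 lower with CSC A at 2 h, 97 and 218 at 4 h, 18 and 68 at 8 h, and 0 at 12 h. Probes at an unadjusted p under 0.05 did not fall in the same way: they were 1950 at 2 h, 2187 at 4 h, 2555 at 8 h and 1363 at 12 h. Limma's F test of whether the difference changed between times, added after these counts were seen, called 132 probes. Leaving out 1 array made this 27 or 303 (CSC A at 2 h replicate 1 or 2), 66 (CSC A at 8 h replicate 2), 36 (CSC B at 2 h replicate 1), 673 (CSC B at 8 h replicate 2) or 63 (CSC B at 12 h replicate 2). Centring of the subgrids gave 61 and 232 at 2 h and 70 and 282 at 4 h, and no normalization gave 1 and 199 at 4 h and 2 and 37 at 8 h. At 2 h the total of 694 became 189 without CSC A replicate 1, and 224 and 452 without CSC B replicates 1 and 2. At 4 h 315 became 70 without CSC A replicate 1, and 1235 and 67 without CSC B replicates 1 and 2. The 86 at 8 h became 17 and 27 without CSC A replicates 1 and 2, and 6 and 1858 without CSC B replicates 1 and 2. At 12 h the count of 0 became 7 and 151 without CSC A replicates 1 and 2, and 13 and 2 without CSC B replicates 1 and 2. A fit on only the arrays of the comparison gave 0 at 8 h.

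S9 only was set against untreated cells to ask what S9 itself does. Untreated cells were taken at 0 h alone, so S9 and time in culture cannot be told apart. Over the 4 times 180 probes were higher and 105 lower with S9 (8 arrays against 2, limma adjusted p under 0.05), of which 59 rose and 10 fell by at least 2-fold. The rises that ranked first were on the probe annotated to POU3F1, from 4.03 ± 0.04 (SD, n = 2) to 6.86 ± 0.39 (SD, n = 8), a difference of 2.83 with an SE of 0.31 and a limma adjusted p of 3.94e-05, and on that annotated to GTSF1, by 2.24 (SE 0.25, limma adjusted p = 4.91e-05). The POU3F1 probe was not above background in untreated cells, so its size and rank are set by the pseudocount, with 1.36 at a pseudocount of 64, while GTSF1 was then at 2.02. The largest falls were -1.41 (SE 0.2, limma adjusted p = 0.000352) on the probe annotated to LIF-AS2 and -1.31 (SE 0.33, limma adjusted p = 0.0347) on that annotated to TXNDC15. Scaling to the 75th percentile gave 294 probes higher and 88 lower. Without untreated replicate 1 the total of 285 became 43, of which 40 were higher, and the LIF-AS2 and TXNDC15 differences, at -1.16 and -1.05, no longer passed. For this comparison the array set term is the same fit as leaving out untreated replicate 1, so its equal values are no further check. The TXNDC15 call was also lost without untreated replicate 2 or without any 1 of 5 S9 only arrays (2 h replicate 2, 4 h replicate 1, 8 h replicates 1 and 2, 12 h replicate 1), with values from -1.22 to -1.58. Without S9 only at 2 h replicate 2 the total became 186. Unnormalized values, in which the untreated arrays were the brightest, gave 12 higher and 8899 lower, with a median over all probes of -0.996.

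The difference between S9 only and untreated cells was larger in number at each later time. At 2 h 0 probes passed by limma, with 757 at an unadjusted p under 0.05, and 46 were higher and 7 lower at 4 h, 120 and 41 at 8 h and 372 and 116 at 12 h. Limma's F test called 126 probes that changed between the 4 S9 only times. The probe annotated to GTSF1 was higher than in untreated cells by 1.69, 2.68 and 3.64 at 4, 8 and 12 h (SE 0.32 each, limma adjusted p = 0.0202, 0.00024 and 1.38e-06). Against untreated replicate 2 alone, which lies in the array set of the S9 only arrays, 1 probe was higher and 0 lower at 2 h, 5 and 0 at 4 h, 35 and 4 at 8 h and 134 and 9 at 12 h, where the lone array is assumed to vary like the other groups. Leaving out untreated replicate 1 is this same comparison, so its totals below are no further check. Scaling to the 75th percentile gave 611 higher and 88 lower at 12 h. Unnormalized values gave 0 and 26 at 2 h, 3 and 6055 at 4 h, 9 and 8133 at 8 h and 28 and 8447 at 12 h. The count of 0 at 2 h became 1 without untreated replicate 1, 30 without untreated replicate 2 and 2 without S9 only replicate 1. At 4 h 53 became 5 without untreated replicate 1 and 19 without S9 only replicate 2. At 8 h 161 became 39 and 268 without untreated replicates 1 and 2, and 95 and 56 without S9 only replicates 1 and 2. At 12 h 488 became 143 without untreated replicate 1, and 246 and 180 without S9 only replicates 1 and 2. The 126 became 77 without S9 only at 2 h replicate 2, 75 without S9 only at 4 h replicate 2, and 37 and 21 without S9 only at 12 h replicates 1 and 2.

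The 25 gene lists gave no call. Of 100 tests, limma's camera passed 0 at a preset correlation, with adjusted p from 0.99 to 0.997, and 0 with an estimated correlation (lowest adjusted p = 0.99). Of 237 probes annotated to list members, 36.7% were called for CSC A against 35.8% of all tested probes, and 47.3% for CSC B against 54%. These differences were not tested. Of 18 probes annotated to antioxidant genes of the NRF2 response, 6 were higher and 4 lower with CSC A, and 7 higher and 2 lower with CSC B. Of 4 annotated to aryl hydrocarbon receptor targets, 0 were higher and 1 lower with CSC A, and 0 higher and 2 lower with CSC B. Among 11 annotated to heat shock genes, 3 were higher and 0 lower with CSC A, and 1 higher and 2 lower with CSC B. Summed over lists, the probes called when adjusted over the list alone were 88 for CSC A, 112 for CSC B, 54 for CSC A against CSC B and 11 for S9 only against untreated. The self-contained test, fry, which asks whether a set moves on balance 1 way and does not compare it with other probes, passed 22 of 100. In 50 draws of 25 random lists of the same sizes it passed 10 to 41, with a median of 23. In 21 of the 100 tests the list's median and camera's direction had opposite signs.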

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

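The tests of the array sets, of grid position, of array background, of replicate spread and of the annotation were chosen after the result was seen; the counts of other splits of the arrays were fixed before. No group had as many as 4 arrays, so no array was tested as an outlier within its group.

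CSC A differed from CSC B on 2289 probes over the 4 times, on 694 at 2 h, on 315 at 4 h and on 86 at 8 h, and on 0 at 12 h by limma. At an unadjusted p under 0.05 the numbers were 1950, 2187, 2555 and 1363 at 2, 4, 8 and 12 h, so only the adjusted counts fall at each step in the reported setting. From 2 to 4 h the adjusted counts rose with subgrid centring, without normalization and in a fit on only the arrays of the comparison. The total over the 4 times fell by more than 1.5 times without 1 of 5 arrays, to as few as 1258 without CSC B at 4 h replicate 2.

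A wider spread between replicates at 12 h is argued against as a reason for the fall to 0. The model gives each probe 1 spread over all groups, so the median SE was 0.228 at each of the 4 times. A wider spread at 12 h alone therefore could not widen the 12 h test. The pair SDs, which do not decide this, were mixed. The median pair SD at 12 h was 0.948 times that at the earlier times as a ratio of means over groups and 1.04 times as a ratio of medians. It was 1.24 times for CSC A and 0.755 times for CSC B, each from 1 pair at 12 h. CSC A changes array set between 8 and 12 h, and the array set may therefore produce the differences at 2, 4 and 8 h. If it did so through position on the slide, the subgrid of a probe should explain more of the difference then. The subgrid explained 25.2%, 13.3% and 13.7% of the variance at 2, 4 and 8 h against 11.8% at 12 h, where shuffled positions gave at most 0.76%. The gap of 1.49 points between the lowest of these shares and that at 12 h is less than 2 bootstrap SDs of 0.88. The larger gap at 2 h was not tested. The array set and a difference between the condensates that ends by 12 h cannot be told apart, since the design has no CSC A array of the earlier times outside that set. Subgrid centring left 293, 352 and 116 probes at 2, 4 and 8 h and 11 at 12 h.

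A chance split of these arrays is argued against for the averaged differences, at the level that 100 splits allow. Chance between cultures is not covered, since the labels do not say whether replicates came from separate cultures. Among 100 splits of the arrays within times, the real split was the 1 with as many probes for CSC A against S9 only (3477, highest other 1728), for CSC B against S9 only (5240, highest other 4614) and for CSC A against CSC B (2289, highest other 2275). The highest other splits came close to the real counts for CSC B against S9 only and closer still for CSC A against CSC B, so a split other than that by arm parts these arrays nearly as well. A chance split does not stand for the array sets, which the arms follow.

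The differences of both condensates from S9 only, 3477 and 5240 probes, coincide with array sets. CSC B shares a set with untreated replicate 1. As the whole cause of its averaged difference, an offset that untreated replicate 1 shares with the CSC B arrays is argued against. Over called probes the untreated difference followed the contrast with a slope of 0.093 (SE 0.008), where the whole cause needs a slope of 1. This slope rests on 1 untreated array in each set and does not cover single times. Its SE takes probes as independent, which they are not. The set of CSC B is made of the arrays outside both marked patterns. An offset of the CSC B arrays that untreated replicate 1 lacks is therefore not covered. Against the untreated array of its own set, CSC B differed on fewer probes at 2 and 4 h than at 8 and 12 h, as given below. Its peak against S9 only at 4 h, with 1005 probes higher and 1455 lower, was not seen there. That comparison rests on 1 untreated array and holds S9 and time as well, so the cause of the peak stays open. For CSC A the slope of the untreated difference was 0.397 (SE 0.01), with the same sign on 68.1% of called probes. There an offset stays open, since no untreated array lies in the set of its arrays at 2, 4 and 8 h. Background of single arrays stays open. Within the 12 replicate pairs of the 3 arms, the array with more spots below 0 minus its partner was correlated with the contrast at the other times. The median r was 0.29 for CSC B and 0.214 for CSC A. For the CSC B contrast r ran from 0.407 to 0.6 in the 4 CSC B pairs and was as low as -0.505 in an S9 only pair. In the S9 only pairs the shares differed by only 0.05 to 0.73 points, so which array has more is hardly set there. With a term for the set of S9 only, 3 and 4 probes passed. The SE rose, and the difference itself shrank or reversed on some probes, such as those annotated to ADAM15 and TUBB6. Over called probes the median difference went from 0.457 to 0.341 for CSC A (SE from 0.115 to 0.342, 86.7% with the same sign). For CSC B it went from 0.503 to 0.546 (SE from 0.118 to 0.354, 93.3%). These probes were called by the same contrast without the term, and the term only brings in the difference of the untreated pair. Most signs could be kept for that reason alone, so these values do not decide whether CSC B had a response.

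Measurement noise is argued against as the reason that the annotated names hardly ordered the intensities, since replicate arrays correlated at 0.96 or more. Rows out of step with the annotation could give the chance of 0.543 that a probe of a widely expressed family was brighter, with an interval of 0.487 to 0.6. Other values go against it: all 22 sets of rows with identical values and an accession shared 1 accession, and different rows correlated at r = 0.083 (permutation p = 0.0009) with the same symbol and at r = 0.319 (permutation p = 0.0128) with the same accession, where rows out of step throughout would give 0. The cause therefore stays open. No biological explanation was tested, since the design gives none for it.

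The difference of CSC A from S9 only changed between times on 39 probes, that of CSC B on 1 and S9 only itself on 126, each by limma's F test. The 39 became 1 within 2, 4 and 8 h, where CSC A stays in 1 array set. By leaving out single arrays these became 1 to 79, 0 to 17 and 21 to 126, the lowest without S9 only at 12 h replicate 2 for CSC A and for S9 only, and without CSC B or S9 only at 2 h replicate 2 for CSC B. The probe annotated to PSD3 differed between CSC A and CSC B by -3.78, and its difference between CSC A and S9 only changed with time at a limma adjusted p of 0.0293, on a probe near the floor with CSC A at 2 h. The probe annotated to CDCA5 differed by -2.15, and its difference between CSC A and S9 only changed with time at a limma adjusted p of 0.0176. It is 1 of the 17 probes that define the set of CSC A at 2, 4 and 8 h, so this change restates the change of set. The probes annotated to CDH7, UROS and HMOX1 were higher with CSC A than with CSC B by 0.58, 0.34 and 0.34, and the HMOX1 call was lost under 5 alternatives and without any 1 of 10 arrays.

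Rows without a single gene symbol, which the report leaves out, also differed. Of 2688 such rows above the intensity filter, 1062 were called for CSC A against S9 only, 1521 for CSC B against S9 only, 518 for CSC A against CSC B and 111 for S9 only against untreated cells.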

How the results depend on the processing

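Fixed before the data were examined were no filter, the pseudocounts, all rows, the intensity trend, the replicate block, fits on the arrays of a comparison, single arrays left out, the estimated correlation and fry for lists, and the split of the S9 only arrays. The 60th percentile filter, no normalization, 75th percentile scaling, the array set term, subgrid centring, the 3 arrays with most spots below 0 and the restriction to 2, 4 and 8 h were added after seeing the data. Counts stayed within 1.5 times of the reported ones for 23 of 23 results with a pseudocount of 1 and for 23 of 23 with a pseudocount of 64. They did so for 24 of 25 with 75th percentile scaling, 22 of 24 with the replicate block, 21 of 23 with an intensity trend, 19 of 23 with all rows and 19 of 23 with subgrid centring. The 60th percentile filter kept 17 of 23, no filter 11 of 23 and leaving out the 3 arrays with most spots below 0 kept 8 of 23. With no normalization 3 of 25 did, with the array set term 8 of 23, which are CSC A against CSC B and the changes between times, that the term could hardly move by its construction, and with fits on the arrays of a comparison alone 7 of 23. Of the values of the named probes under all alternatives, 556 kept direction and side of the threshold, 34 no longer passed, 1 newly passed and 14 changed sign. Below, counts are probes past a limma adjusted p of 0.05, "on average" means over the 4 times, and values not given stayed within 1.5 times. The cause was not tested, except where named.

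Without normalization, CSC A against S9 only gave 1441 on average, 308 at 2 h, 51 at 4 h, 49 at 8 h and 60 at 12 h. Without normalization, CSC B against S9 only gave 3460 on average, 14 at 2 h, 481 at 4 h, 466 at 8 h and 939 at 12 h. Without normalization, CSC A against CSC B gave 735 on average, 152 at 2 h, 200 at 4 h and 39 at 8 h. Without normalization, S9 only against untreated gave 8911 on average, 26 at 2 h, 6058 at 4 h, 8142 at 8 h and 8475 at 12 h. Without normalization, probes that changed between times were 25 for CSC A, 0 for CSC B and 32 for S9 only. Array medians then enter the contrasts.

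With no filter, CSC A against S9 only gave 6366 on average, 3593 at 2 h, 939 at 4 h, 503 at 8 h and 1584 at 12 h. With no filter, CSC B against S9 only gave 8253 on average, 1443 at 2 h, 4055 at 4 h, 2863 at 8 h and 940 at 12 h. With no filter, S9 only against untreated gave 10 at 2 h. With no filter, probes that changed between times were 3 for CSC A. The number of probes tested was larger there, which does not by itself set these counts. CSC A against CSC B stayed at 2251 on average, against 2289 in the reported setting. Filtered at the 60th percentile, CSC A against S9 only gave 994 at 2 h and 318 at 12 h. Filtered at the 60th percentile, CSC B against S9 only gave 3473 on average. Filtered at the 60th percentile, CSC A against CSC B gave 159 at 8 h. Filtered at the 60th percentile, S9 only against untreated gave 9 at 2 h. Filtered at the 60th percentile, probes that changed between times were 61 for CSC A. Fewer probes were tested there, yet some of these counts lay above the reported ones, so the number tested does not set them alone. On all rows, CSC B against S9 only gave 491 at 2 h and 643 at 12 h. On all rows, CSC A against CSC B gave 25 at 12 h. On all rows, probes that changed between times were 3 for CSC B.

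With the array set term, CSC A against S9 only gave 3 on average, 2 at 2 h, 2 at 4 h, 1 at 8 h and 1 at 12 h. With the array set term, CSC B against S9 only gave 4 on average, 2 at 2 h, 2 at 4 h, 3 at 8 h and 6 at 12 h. With the array set term, S9 only against untreated gave 43 on average, 1 at 2 h, 5 at 4 h, 39 at 8 h and 143 at 12 h. For S9 only against untreated this is the same fit as leaving out untreated replicate 1. The term sets S9 only and untreated replicate 2 apart, so the SE includes that of single untreated arrays, and it measures no offset of CSC A at 2, 4 and 8 h. Under it the ADAM15 and TUBB6 probes changed sign to -0.38 and -0.27 for CSC A and to -0.58 and -0.34 for CSC B, and the CYP1B1 probe to -0.11 for CSC A. The CYP1B1 probe for CSC B, at -0.01 (limma adjusted p = 0.949) no call, changed sign with subgrid centring to 0.11, without the 3 arrays to 0.09, and without 1 of 7 single arrays to between 0 and 0.06, the values being 0.03, 0.02, 0.06, 0, 0.03, 0.01 and 0.01. Over all 16 single arrays it ran from -0.08 to 0.06. With subgrid centring, CSC B against S9 only gave 695 at 12 h. With subgrid centring, CSC A against CSC B gave 293 at 2 h and 11 at 12 h. With subgrid centring, probes that changed between times were 3 for CSC B.

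Without the 3 arrays with most spots below 0, CSC A against S9 only gave 494 at 4 h, 297 at 8 h and 1007 at 12 h. Without the 3 arrays with most spots below 0, CSC B against S9 only gave 796 at 2 h, 37 at 4 h, 256 at 8 h and 977 at 12 h. Without the 3 arrays with most spots below 0, CSC A against CSC B gave 697 on average, 1101 at 2 h, 115 at 4 h, 3 at 8 h and 24 at 12 h. Without the 3 arrays with most spots below 0, S9 only against untreated gave 3 at 2 h and 84 at 4 h. Without the 3 arrays with most spots below 0, probes that changed between times were 247 for CSC A. They are CSC B at 8 h replicate 1, CSC A at 2 h replicate 2 and CSC B at 4 h replicate 2, and each leaves its group with 1 array. Fitted on its own arrays, CSC A against S9 only gave 472 at 8 h and 184 at 12 h. Fitted on its own arrays, CSC B against S9 only gave 5 at 2 h, 591 at 4 h, 4 at 8 h and 2 at 12 h. Fitted on its own arrays, CSC A against CSC B gave 1384 on average, 24 at 2 h, 119 at 4 h and 0 at 8 h. Fitted on its own arrays, S9 only against untreated gave 1 at 2 h, 1 at 4 h, 63 at 8 h and 208 at 12 h. Fitted on its own arrays, probes that changed between times were 161 for CSC A and 3 for CSC B. Such fits have fewer residual degrees of freedom. With an intensity trend, CSC A against CSC B gave 141 at 8 h. With an intensity trend, S9 only against untreated gave 5 at 2 h. With 75th percentile scaling, CSC A against CSC B gave 152 at 8 h. Within 2, 4 and 8 h, 1 probe changed between times for CSC A.

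Replicate numbers did not pair the arrays: of 78 pairs of groups the deviations of same-numbered arrays correlated over 0.1 in 22 and under -0.1 in 25, from -0.5 to 0.52. With the replicate block, CSC B against S9 only gave 189 at 2 h. With the replicate block, S9 only against untreated gave 35 at 4 h. The block changed no other count by over 1.5 times. With the S9 only arrays split, replicate 2 against A, the correlation of the CSC A and CSC B effects was 0.624. Fry passed 22 of 100 list tests.

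Over single arrays left out, CSC A against S9 only ran from 2744 to 3411 on average, 163 to 1414 at 2 h, 36 to 280 at 4 h, 27 to 75 at 8 h and 11 to 315 at 12 h. Over single arrays left out, CSC B against S9 only ran from 4502 to 5518 on average, 4 to 410 at 2 h, 8 to 3351 at 4 h, 68 to 2672 at 8 h and 8 to 406 at 12 h. Over single arrays left out, CSC A against CSC B ran from 1258 to 3156 on average, 189 to 841 at 2 h, 67 to 1235 at 4 h, 6 to 1858 at 8 h and 2 to 151 at 12 h. Over single arrays left out, S9 only against untreated ran from 43 to 333 on average, 0 to 30 at 2 h, 5 to 71 at 4 h, 39 to 268 at 8 h and 143 to 573 at 12 h. Probes that changed between times ran from 1 to 79 for CSC A, 0 to 17 for CSC B and 21 to 126 for S9 only. Where this leaves a group with 1 array, that array is assumed to vary like the other groups. Signal near background limits dim probes, since spots below 0 carry no level.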

Other observations

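The tests of change with time within an arm, of background against the first principal component and of neighbouring positions were chosen after the data were seen. The prediction for CSC A in the next paragraph was written before its value was seen.

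Change with time was compared within arms whose arrays lie in 1 set. Within the S9 only arrays 130 probes were higher and 8 lower at 12 h than at 2 h, and within the CSC B arrays 90 were higher and 67 lower (2 arrays against 2, limma adjusted p under 0.05). These lists share no array, and 37 probes were higher in both, where independent lists would share 1.21. The model gives each probe 1 spread for both tests, so the lists are not fully independent and 1.21 may be too low a reference. The largest rise in S9 only among them was on the probe annotated to GTSF1, 2.71 (SE 0.32, limma adjusted p = 0.000149), which rose by 1.38 with CSC B (SE 0.32, limma adjusted p = 0.0357). Next came the probes annotated to RASGRF1, with 2.16 and 1.36, and to LIG1, with 2.15 and 1.94. Across all 9708 probes, which are not independent replicates, the changes from 2 to 12 h in the 2 arms correlated at r = 0.311.

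The hypothesis that this rise is common to all S9 arms was tested in CSC A, whose arrays at 2 and 8 h lie in 1 set and took no part in choosing the 37 probes. Their median change from 2 to 8 h with CSC A was 1.02 log2, with 37 of 37 higher and 28 called higher by limma, against a median of 0.059 and a 95% range of -0.1 to 0.2 for 10000 random lists of 37 probes. Over all tested probes 349 were called higher and 168 lower at 8 h than at 2 h with CSC A, 1 and 0 in S9 only, and 27 and 7 with CSC B. The changes from 2 to 8 h correlated at r = -0.016 between S9 only and CSC A and at -0.076 between CSC A and CSC B. Between S9 only and CSC B r was 0.384. The likeness of CSC A to the other arms may therefore be limited to these probes. With 75th percentile scaling the median was 1 and with subgrid centring 1.04, with 37 of 37 higher in both, while unnormalized values gave 32 of 37 and a median of 0.56 against -0.38 over all probes. On unnormalized values the probes called in both S9 only and CSC B were 2 higher and 24 lower at 12 h than at 2 h, a setting in which shifts of whole arrays enter every change. The number of probes shared by S9 only and CSC B became 3 without CSC B at 2 h replicate 2, 7 and 11 without CSC B at 12 h replicates 1 and 2, 16 and 21 without S9 only at 2 h replicates 1 and 2, and 22 and 15 without S9 only at 12 h replicates 1 and 2. A response to S9 that grows and a change with time in culture cannot be told apart here, as no untreated cells were taken after 0 h.

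CSC B was also set against untreated replicate 1, the untreated array of its own set. Over the 4 times 396 probes were higher and 392 lower, with 22 and 58 at 2 h, 11 and 10 at 4 h, 521 and 694 at 8 h and 592 and 528 at 12 h by limma, where the lone untreated array is assumed to vary like the other groups. This comparison holds S9, the condensate and time together.

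The first principal component took 36.8% of the variance. Within the 11 arrays outside both of the marked sets, it correlated with the share of spots below 0 at r = 0.75 (permutation p = 0.00815, adjusted over 3 sets 0.0244) and rho = 0.7 (permutation p = 0.0203, adjusted 0.0608). Without the 2 arrays farthest from the median share, r was 0.389, so the relation rests on those arrays. Within the 6 arrays of CSC A at 2, 4 and 8 h r was 0.608 (exact permutation p = 0.194, adjusted 0.292) and rho 0.771 (exact permutation p = 0.103, adjusted 0.154), with r = 0.425 without the 2 farthest. Within the 9 arrays of S9 only and untreated replicate 2 r was 0.108 (exact permutation p = 0.776, adjusted 0.776) and rho 0.167 (exact permutation p = 0.678, adjusted 0.678), with r = -0.317 without the 2 farthest.

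Among the 38 probes that part the S9 only arrays and untreated replicate 2 from the rest, 3 pairs lay on neighbouring positions of the slide. Of 10000 random draws of as many positions, 21 had that many pairs, with a mean of 0.247.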
